A study of Mus musculus with 28 samples.

How the data were processed

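CUT&RUN libraries came from nuclei of E14 mouse embryonic stem cells, per the labels' protocols. The 28 libraries were placed in groups by target and genotype from their titles. Per the labels' protocols, H3K27ac and H3K122ac libraries used a protein A fusion of micrococcal nuclease and H3.3 libraries a protein A/G fusion, digestion for H3K27ac was stopped in a buffer with more salt than for the other targets, and yeast mononucleosomes were added as a spike-in. Bowtie2, SAMtools, deepTools and MACS2 and the genome build mm10 are named, per the submitters' processing notes, without versions or roles. How regions of single libraries were combined into a consensus, which genotypes entered it, and any threshold or exclusion list are not given in the sources used here.

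The deposited values are the chromosome, start and end of each consensus region, 1 list for H3.3 and 1 for H3K27ac, without a header, score, height or p-value and without a value per library. Regions within a list do not overlap, and merging touching ones left both counts as they were. Columns of other samples numbered 0. Because the lists hold no per-library values, the comparison of mutant genotypes with wildtype, the H3K122ac libraries and the controls without antibody were not analysed here, depth is unknown, and no background could be set beside the regions. Whether a region is present in wildtype, in mutants or in both is likewise unknown. Starts were raised by 1 to give 1-based coordinates.

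Gene positions, biotypes and symbols came from the RefSeq table of the mouse assembly GRCm38.p6, whose primary chromosomes carry the coordinates of mm10. It held 49943 genes on the 21 assembled chromosomes, 21887 of them protein-coding. The table gives no strand, start site or exons. The promoter test planned before the data were examined was therefore run on gene ends, defined as the sequence within 1 kb of either annotated end of a gene, and a region could not be placed in an exon, intron or UTR. A mark counted as present at a gene if any region touched this window by 1 bp or more. Widths and rankings within gene lists are those of regions that touch this window, so a wider region inside a gene does not enter. For the classes of regions, the centre of a region was placed at a gene end, inside a gene or between genes, over genes of all biotypes. Regions on the mitochondrial genome and unplaced scaffolds, 16 for H3.3 and 13 for H3K27ac, were left out of every comparison.

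Overlap of the sets was tested by shifting the H3.3 regions by a random distance around each chromosome, within the span of the regions, in 1000 circular shifts, which keep the spacing of regions. The two-sided permutation p has 0.002 as its smallest value. Classes were compared with 100 random placements. Gene lists were tested with two-sided Fisher's exact tests against all other protein-coding genes, with Benjamini-Hochberg adjustment over the 36 tests of 18 lists and 2 sets. Odds ratios had 0.5 added to each cell where a cell was 0. Intervals of shares are exact (Clopper-Pearson) at 95% and cover counting over regions or genes only. H3K27ac regions closer than 12.5 kb were joined into clusters and ranked by the length of regions they held.

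Of the lists, 13 were typed by name before the data were examined (315 names, of which 5 were not found in the gene table) and 5 were defined by the start of the gene symbol. Some imprinted genes are not protein-coding and were counted in their list. The rule for named genes, also set before the data were examined, took the 10 widest regions of each set with the nearest protein-coding gene, the 10 clusters with the most H3K27ac, the 10 genes with the widest H3.3 region at an end and no H3K27ac there, up to 4 members of each list with a region (widest first) and up to 4 without (alphabetical), and H3f3a and H3f3b. Names given beyond it are complete sets of 5 or fewer genes, or Tbx5 and Grb10, which complete such sets, and were chosen after the values were seen. Some genes that the rule takes are not reported here.

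Both tests were tested on simulated data that were simpler than the real sets. Unrelated regions were scattered at random and genes were marked independently. Clustered regions and neighbouring genes that share a region were therefore not covered. Fewer than 1000 shifts were used, and adjustment was over fewer than 36 tests. The rates that follow are thus not error rates of the tests as run. Among 40 sets of 5430 regions placed without regard to H3K27ac, the shift test called 2 at p under 0.05, and with 5% of the regions planted on H3K27ac regions it called 40 of 40. When 50% of the 40 lineage regulators were given a mark, the list test over 21887 protein-coding genes called that list in 194 of 200 simulations, and it called 0.471% of 3400 unchanged lists. Alternatives covered the overlap rule, the null, the gene-end window (500 bp and 2.5 kb), protein-coding genes alone, the wider 50% of each set, H3K27ac regions reduced to 200 bp, the background of genes with H3K27ac and a joining distance of 5 kb. Added after the data were seen were regions anywhere in the gene, shifted regions in place of other genes, autosomes alone, list members at least 1 Mb apart (the members left out then count among the other genes), extraembryonic markers without the lineage regulators, and classes by touching. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.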

Results

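Chromatin carrying the histone variant H3.3 and chromatin carrying acetylated histone H3 were mapped by CUT&RUN in mouse embryonic stem cells of the male line E14. In CUT&RUN an antibody directs a tethered nuclease to its target in isolated nuclei, and the released DNA fragments are sequenced. H3.3 is the histone H3 variant deposited outside DNA replication and is encoded by H3f3a and H3f3b. H3K27ac is acetylation of lysine 27 of histone H3, a mark of active promoters and enhancers. The 28 libraries covered 4 targets, which were H3K27ac, H3K122ac, H3.3 and a control without primary antibody, with 7 libraries each. For each target, wildtype cells had 2 libraries, the genotype with both H3f3a alleles and 1 H3f3b allele labelled A had 2, from 2 clones, and each of the other 3 mutant genotypes had 1. The values analysed were the positions of 2 sets of consensus regions, 1 for H3.3 and 1 for H3K27ac. They carry no value per library, so the comparison of mutant with wildtype cells and the H3K122ac and control libraries were not analysed here. Read depth is unknown, and there are no replicates behind any count below. Intervals are exact 95% intervals over regions or genes, and p-values describe these 2 region sets, not the spread between cultures.

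H3.3 regions were few and short, and H3K27ac regions were many and long. The H3.3 set held 5446 regions covering 4.03 Mb, with a median width of 452.5 bp and an interquartile range of 255 to 819 bp. The H3K27ac set held 57857 regions covering 77.6 Mb, with a median width of 812 bp and an interquartile range of 412 to 1574 bp. The H3K27ac set thus had 10.6 times as many regions and covered 19.4 times as much sequence. Regions wider than 5 kb numbered 56 for H3.3 and 1990 for H3K27ac. The digestion was stopped with different salt conditions and a different nuclease fusion was used for the 2 targets, so the set sizes do not compare amounts of chromatin.

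The widest H3.3 regions lay over genes for embryonic patterning factors. The widest of all, at 13931 bp, spanned Uncx, a homeobox gene of the somites and nervous system, on chromosome 5 from 139540178 to 139554108 (mm10). It was followed by a region of 12043 bp at Six3, a forebrain and eye regulator, on chromosome 17 from 85612109 to 85624151. Otx1, Cbx8, Lhx5, Tfap2a, Skor1, Pax2 and Pax7 were also among the 10 widest, down to 9167 bp at Pax7. Cbx8 encodes a chromobox subunit of Polycomb repressive complex 1, and Uncx, Six3, Otx1, Lhx5, Tfap2a, Skor1, Pax2 and Pax7 encode transcriptional regulators. None of the regions named here touched an H3K27ac region. Dlx2 (8763 bp) and the neighbours Hoxb5 and Hoxb6 (a shared region of 8656 bp) were also among the 10 genes with the widest H3.3 region at a gene end and no H3K27ac region there.

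The widest H3K27ac regions lay over a different group of genes. The widest covered 45403 bp of Tns3, which encodes a focal adhesion protein, on chromosome 11 from 8552240 to 8597642. The next were 41598 bp at Zfp532 and 39271 bp at Esrrb, an orphan nuclear receptor of the naive pluripotency network, on chromosome 12 from 86470160 to 86509430. Atf1, Etv5, N4bp1, Etl4, Enah and the pair Rab1a and Cep68 followed, down to 26987 bp at Rab1a and Cep68. Of the regions named here, those at Tns3, Esrrb, Etv5, Etl4 and Rab1a with Cep68 touched an H3.3 region.

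Joining neighbouring H3K27ac regions gave 15441 clusters, of which 183 held more than 50 kb of H3K27ac regions. The cluster at Tns3 held the most, 190.5 kb in 40 regions between 8429634 and 8679193 on chromosome 11. The cluster reaching from Ppp2r5c to Zfp839 on chromosome 12 held 178.3 kb, and that of Jarid2, a Polycomb repressive complex 2 subunit, and Dtnbp1 on chromosome 13 held 165.2 kb. Clusters at Pitpnc1 with Psmd12 and Helz (156.6 kb), at Ncor1, a nuclear receptor corepressor gene, and its neighbours (148.8 kb), at Adk with the acetyltransferase gene Kat6b (148.2 kb), at the RNA-binding protein gene Msi2 (141.9 kb), at Etl4 (139.3 kb) and at Itpk1 with its neighbours (126.95 kb) were also among the 10 with the most. The ranking uses covered length, since no signal heights were used here, and it depends on the joining distance. Joining at 5 kb gave 25368 clusters, 83 of them with more than 50 kb of H3K27ac regions, and the clusters at Ppp2r5c, Pitpnc1, Ncor1, Etl4 and Itpk1 were then not among the 10 with the most.

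**Figure D1:**
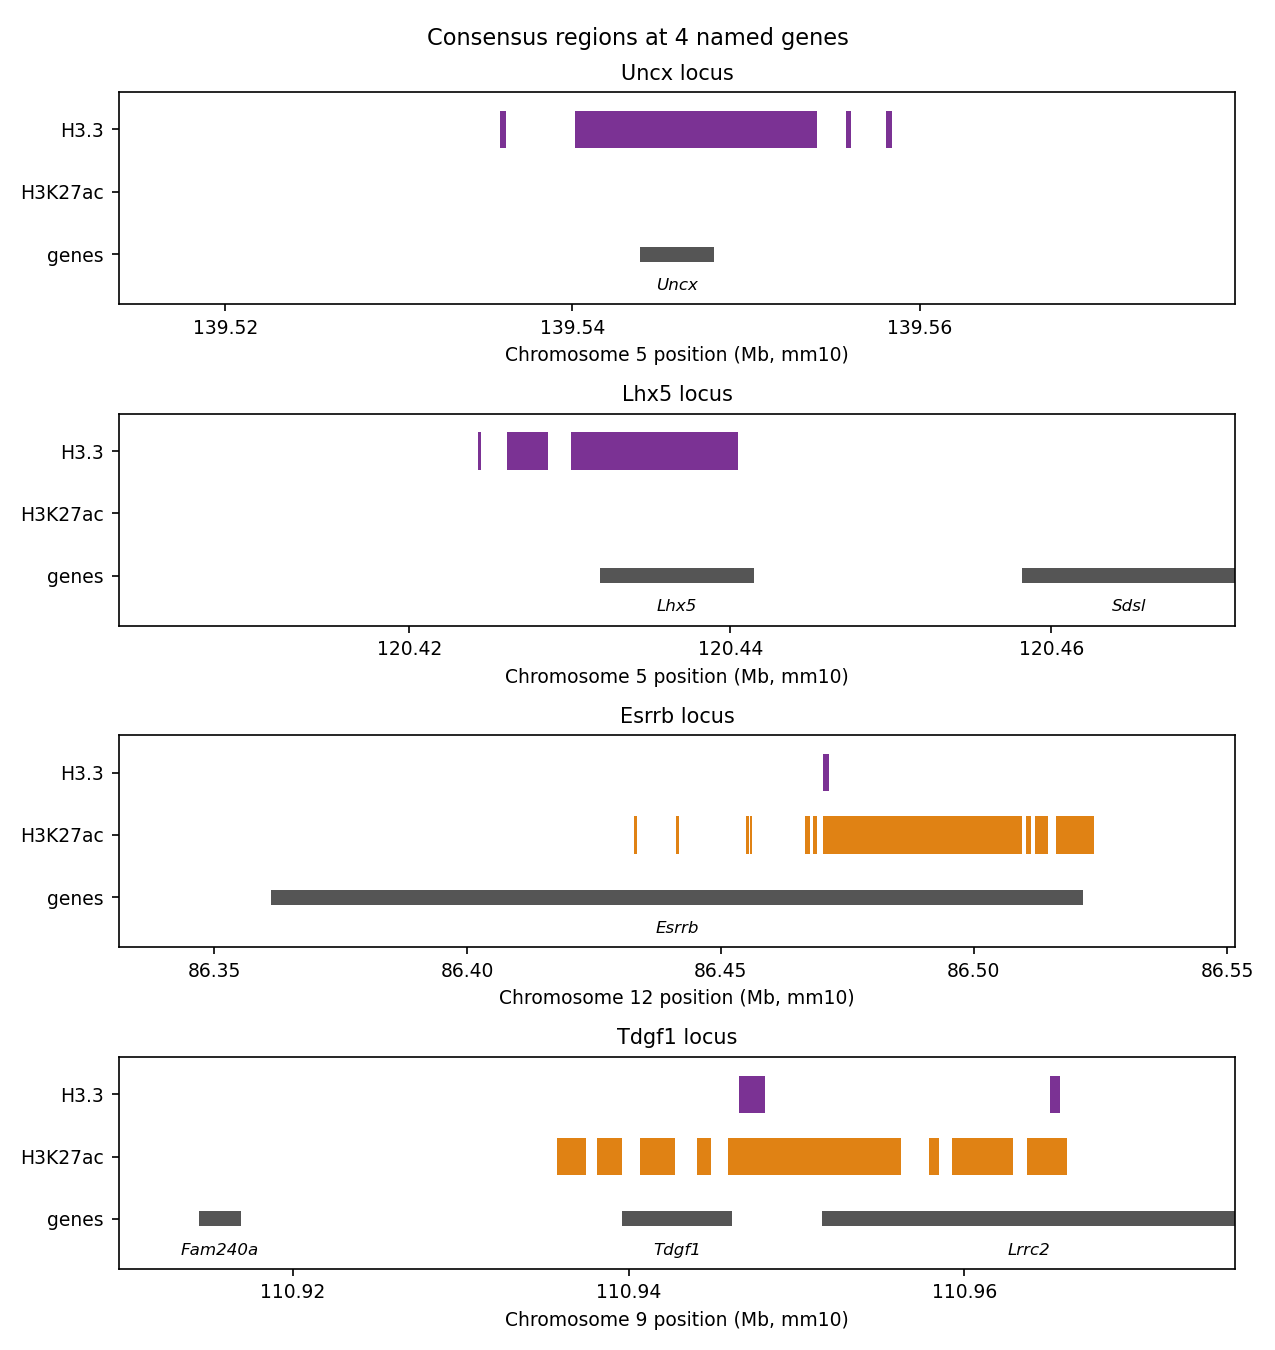
Consensus regions of H3.3 (purple) and H3K27ac (orange) and protein-coding genes (grey) around Uncx, Lhx5, Esrrb and Tdgf1, to scale on mm10 coordinates in Mb. Uncx and Lhx5 carried H3.3 regions of 13931 bp and 10360 bp without H3K27ac, Esrrb carried an H3K27ac region of 39271 bp that touched an H3.3 region, and Tdgf1 carried both at a gene end.

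Whether H3.3 lies where H3K27ac lies was asked of the regions directly. Close to 1 in 2 H3.3 regions touched acetylated chromatin, and the rest did not. Of the 5430 H3.3 regions on assembled chromosomes, 2579 touched an H3K27ac region by at least 1 bp, which is 47.5% (46.2 to 48.8%), and 2851 did not. When the H3.3 regions were shifted around each chromosome 1000 times, a mean of 5.06% and at most 6.59% touched one, so the observed share was 9.38 times the shifted mean (two-sided permutation p = 0.002, the smallest these shifts can give). In the other direction, 2521 of 57844 H3K27ac regions touched an H3.3 region, which is 4.36%. Here a region counted as near a gene end if any part of it lay within 1 kb, unlike the classes by centre below. Of 3515 such H3.3 regions 1671 touched H3K27ac (47.5%), and 908 of 1915 away from gene ends did (47.4%). With 2.5 kb the shares were 45.9% near (44.4 to 47.4%) and 52.7% away (49.9 to 55.5%). At 1 kb the shifted means were 12.1% near gene ends and 4.39% away from them, so the excess was 3.94-fold and 10.8-fold (permutation p = 0.002 for each).

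H3.3 regions sat mainly at gene ends and H3K27ac regions mainly inside genes. A gene end is here the sequence within 1 kb of either annotated end of a gene. By the region's centre, 3201 H3.3 regions (59.0%, 57.6 to 60.3%) lay at a gene end, 1557 (28.7%) inside a gene and 672 (12.4%) between genes. Random placement put a mean of 6.63% at gene ends, so H3.3 regions were 8.89 times as frequent there. For H3K27ac, 9567 regions (16.5%, 16.2 to 16.8%) lay at a gene end, 39732 (68.7%) inside a gene and 8545 (14.8%) between genes, against random means of 6.54%, 45.9% and 47.6%. H3K27ac regions were thus 2.53 times as frequent as random at gene ends and 1.50 times as frequent inside genes. These shares move with the window, from 46.0% to 74.2% for H3.3 and from 9.16% to 28.3% for H3K27ac between windows of 500 bp and 2.5 kb.

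At the level of genes, H3.3 and H3K27ac were found at the same genes more often than if they were unrelated. Of 21887 protein-coding genes, 3495 (16%) had an H3.3 region at a gene end and 8501 (38.8%) an H3K27ac region. Both were present at 2331 genes, H3.3 alone at 1164, H3K27ac alone at 6170 and neither at 12222. A gene counted with both can have them at different ends, so these counts do not show that the marks share a position. H3.3 was present at 27.4% of the genes with H3K27ac and at 8.70% of the others, an odds ratio of 3.97 (3.67 to 4.29; two-sided Fisher's exact test, p = 3.27e-290). Neighbouring genes can share a region, so genes are not independent and this p-value is too small.

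Lineage regulators did not follow that association. This list of 40 transcription factors of germ layers and organs, many of them classical Polycomb targets in embryonic stem cells, had an H3.3 region at 35 genes (87.5%, 73.2 to 95.8%) against 15.8% of other genes, an odds ratio of 37.2 (Fisher's exact test with Benjamini-Hochberg adjustment over 36 tests, adjusted p = 1.93e-22). H3K27ac was present at 1 of the 40 (2.5%, 0.0633 to 13.2%) against 38.9% of other genes (odds ratio 0.0403, exact adjusted p = 3.04e-07). That gene was Mixl1, a primitive streak homeobox gene, whose region measured 177 bp, and Mixl1 had no H3.3 region. At gene ends, the widest H3.3 region of the list was at Lhx5, a forebrain LIM-homeobox gene (10360 bp). Msx1, a craniofacial and limb homeobox gene (7198 bp), and Hand1, a heart and trophoblast factor (5620 bp), followed. The region of 9167 bp at Pax7, also on the list, touched neither end window of Pax7. The median over the 35 genes was 3164 bp, against 486 bp over all protein-coding genes with an H3.3 region. Gata4, Isl1 and Myod1, of endoderm and heart, of motor neurons and of muscle, and the heart and limb factor Tbx5 had neither mark at a gene end. Against regions shifted at random, instead of against other genes, 1 gene with H3K27ac compared with a mean of 4.52 did not pass (permutation, adjusted p = 0.175), so the low count holds relative to other genes and not relative to random sequence.

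Markers of the extraembryonic lineages had H3.3 more often and H3K27ac less often than other genes, and 12 of the 24 had neither. Of 24 primitive endoderm and trophoblast markers, 10 had H3.3 (41.7%, odds ratio 3.77, Fisher's exact test, adjusted p = 0.00431) and 2 had H3K27ac (8.33%, odds ratio 0.143, adjusted p = 0.00247), and no gene had both. Hand1 (5620 bp), the endoderm factor Gata6 (4249 bp), the growth factor receptor gene Pdgfra (3531 bp) and the trophoblast factor Cdx2 (3323 bp) had the widest H3.3 regions. H3K27ac was found at Sparc (1177 bp), a basement membrane protein gene, and at the laminin gene Lamb1 (294 bp). Cubn, Dab2 and Elf5 had no H3.3 region at a gene end. The list shares 5 genes with the lineage regulators. Without them the H3.3 call ended, with 6 of 19 genes (31.6%, 12.6 to 56.6%; odds ratio 2.43, exact adjusted p = 0.119), and H3K27ac at 2 of 19 still passed (odds ratio 0.185, exact adjusted p = 0.0161). Against shifted regions the H3K27ac call of the whole list did not pass, with 2 genes against a mean of 2.91 (permutation, adjusted p = 0.929).

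Naive pluripotency genes carried wide H3K27ac regions. Of the 30 listed, 26 had H3K27ac (86.7%, 69.3 to 96.2%; odds ratio 10.3, Fisher's exact test, adjusted p = 3.04e-07), with a median width of 4991 bp against 1388 bp over all protein-coding genes with the mark. The widest at a gene end were at Fbxo15 (16704 bp) and Dppa5a (12499 bp). The Krüppel-like factor gene Klf5 (10499 bp) and the Nodal co-receptor gene Tdgf1 (10315 bp) came next. The region of 39271 bp at Esrrb, also on this list, was wider but touched neither end window of that gene. Dppa3, Nr0b1, Nr5a2 and Prdm14 had no H3K27ac region at a gene end, although 25 H3K27ac regions lay within Nr5a2 or 1 kb of it and 1 within Dppa3 or 1 kb of it. Nr0b1 is X-linked, and the X chromosome held few regions of either set (below). H3.3 was present at 10 of the 30 (33.3%, odds ratio 2.64, exact adjusted p = 0.0279), with the widest regions at Tbx3 (2347 bp), at Pou5f1, which encodes the core factor OCT4 (1684 bp), at Tdgf1 (1513 bp) and at Lin28a (1395 bp). With a window of 500 bp the H3.3 call of this list did not pass (8 of 30 genes, odds ratio 2.20, exact adjusted p = 0.0848). Of these 10 genes at 1 kb 9 also had H3K27ac, and Prdm14, a regulator of naive and germline identity, had H3.3 alone.

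Formative and primed pluripotency genes, which rise when cells leave the naive state, had H3.3 more often than other genes. It was present at 11 of 19 (57.9%, odds ratio 7.26, Fisher's exact test, adjusted p = 1.01e-04), 8 of them without H3K27ac. The widest H3.3 regions were at Zic2 (6252 bp), the epiblast and forebrain factor Otx2 (5078 bp), the WNT effector gene Lef1 (3559 bp) and Etv4 (1029 bp). H3K27ac was present at 8 of 19, a share of 42.1% that did not differ from other genes (odds ratio 1.15, exact adjusted p = 0.816). At gene ends it was widest at the signalling gene Nodal (6597 bp), Etv4 (6260 bp) and Lefty2 (3353 bp). The wider region at Etv5 (29593 bp) touched neither end window of that gene. H3K27ac was absent from the ends of Cdh2, Dnmt3a, Fgf5 and Foxd3. Even so, 12 H3K27ac regions lay within Dnmt3a or 1 kb of it and 2 within Cdh2 or 1 kb of it.

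**Figure D2:**
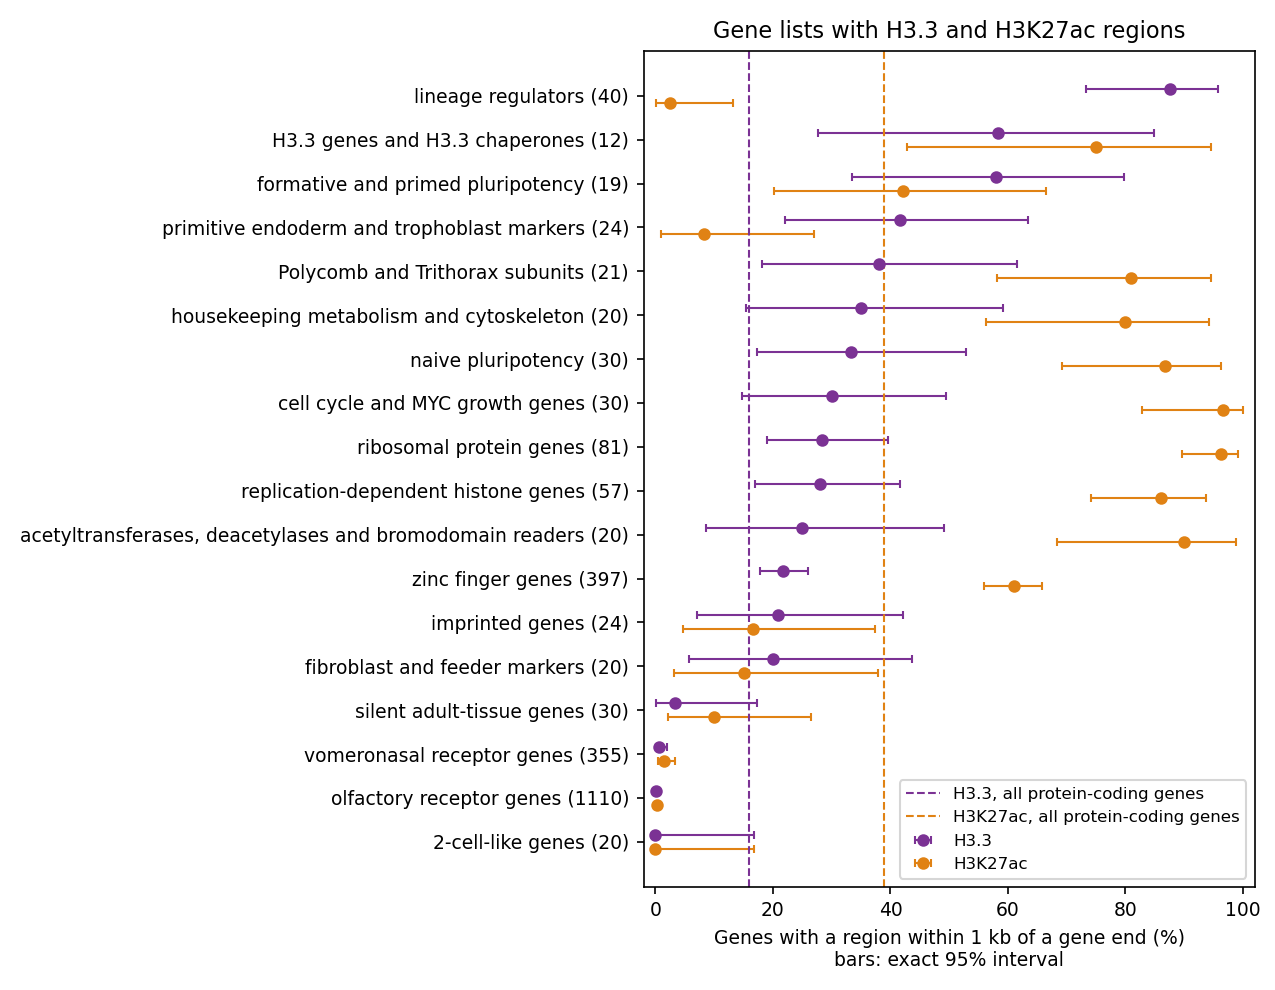
Share of genes in each of 18 lists with an H3.3 region (purple) or an H3K27ac region (orange) within 1 kb of a gene end, in percent, with exact 95% intervals as bars, the number of genes in parentheses and the shares over all protein-coding genes as dashed lines (16% and 38.8%). Lineage regulators stood at 87.5% for H3.3 and 2.5% for H3K27ac, and ribosomal protein genes at 28.4% and 96.3%.

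Growth and housekeeping genes were mostly acetylated. H3K27ac was present at 29 of 30 cell cycle and MYC growth genes (96.7%, odds ratio 45.8, Fisher's exact test, adjusted p = 8.95e-11), with the widest regions at the replicative helicase genes Mcm5 (10015 bp) and Mcm3 (7438 bp), the glycolytic gene Eno1 (5673 bp) and the licensing factor gene Cdt1 (5515 bp). The exception was the cyclin gene Ccnd2, which instead had the widest H3.3 region of that list (5478 bp), ahead of Mcm7 (902 bp), Myc (777 bp) and Mycn (541 bp). Of 81 ribosomal protein genes 78 had H3K27ac (96.3%, odds ratio 41.3, exact adjusted p = 1.35e-27), widest at Rps15a (20529 bp), and the 3 without it were Rpl10l, Rpl32l and Rpl39l. H3K27ac was also present at 49 of 57 replication-dependent histone genes (86.0%, exact adjusted p = 1.13e-12), widest at H4c6 (8160 bp), and at 16 of 20 housekeeping genes (80.0%, adjusted p = 5.94e-04), widest at Gapdh (10745 bp) and Eef1a1 (8962 bp). H3.3 was present at 23 of the 81 ribosomal protein genes (28.4%, odds ratio 2.09, exact adjusted p = 0.00892), 16 of the 57 histone genes (28.1%, odds ratio 2.06, adjusted p = 0.0258), 7 of the 20 housekeeping genes (35.0%, odds ratio 2.84, adjusted p = 0.0400) and 9 of the 30 cell cycle and growth genes (30.0%, odds ratio 2.26, adjusted p = 0.0541). These H3.3 results depend on the settings. The cell cycle and growth list, which did not pass at 1 kb, passed with a 2.5 kb window (13 of 30 genes, odds ratio 3.40, exact adjusted p = 0.00241). It also passed with regions anywhere in the gene (11 of 30, odds ratio 2.37, exact adjusted p = 0.0457), but not with 500 bp (7 of 30, odds ratio 1.84, exact adjusted p = 0.213). The housekeeping call did not pass with a window of 500 bp (5 of 20 genes, odds ratio 2.01, exact adjusted p = 0.215). With the wider 50% of each set the ribosomal call (10 of 81 genes, odds ratio 1.53, exact adjusted p = 0.265) and the histone call (9 of 57, odds ratio 2.04, exact adjusted p = 0.0816) did not pass, the latter with fewer marked genes at nearly the same odds ratio. With regions counted anywhere in the gene the odds ratios were 1.63 and 1.60 (exact adjusted p = 0.0587 and 0.143). Histone genes lie in clusters and share regions, and only 3 lie at least 1 Mb apart. All 3 had both marks (29.2 to 100%), with an H3K27ac odds ratio of 11.0 against 9.69 for the whole list, and with so few genes the H3K27ac call ended (exact adjusted p = 0.0727).

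The genes of the chromatin machinery itself were mostly acetylated. Among H3.3 genes and chaperones, 7 of 12 had H3.3 (58.3%, odds ratio 7.38, Fisher's exact test, adjusted p = 0.00203) and 9 had H3K27ac (75%, odds ratio 4.73, adjusted p = 0.0225). Both marks were found at Hira, which encodes the chaperone for H3.3 deposition at genes, with 1175 bp of H3.3 and 4769 bp of H3K27ac, and at Daxx, the chaperone partner of ATRX, with 1308 bp and 4436 bp. H3f3a carried an H3.3 region of 390 bp and an H3K27ac region of 875 bp at its ends. H3f3b, on chromosome 11 from 116021961 to 116026039, carried neither, and its nearest regions were 3.69 kb away for H3K27ac and 207.9 kb away for H3.3. Of 20 genes for acetyltransferases, deacetylases and bromodomain readers, 18 had H3K27ac (90.0%, odds ratio 14.2, exact adjusted p = 9.14e-06) and 5 had H3.3 (25%, adjusted p = 0.385). The H3.3 result depends on the window. With 2.5 kb 8 of the 20 had H3.3 and the list passed (odds ratio 2.96, exact adjusted p = 0.0241). With 500 bp 3 had it (odds ratio 1.06, exact adjusted p = 0.789). Kat6b had the widest region of that list for both marks, 21172 bp of H3K27ac and 1219 bp of H3.3, and Crebbp and Hdac8 had no H3K27ac at a gene end. Hdac8 is X-linked, so its lack of H3K27ac falls under the same limit as that of Nr0b1. Of 21 Polycomb and Trithorax genes, 17 had H3K27ac (81.0%, odds ratio 6.70, exact adjusted p = 3.19e-04), widest at Kdm2b (12727 bp) and Eed (12055 bp), and 8 had H3.3 (38.1%, odds ratio 3.24, adjusted p = 0.0189), widest at Rbbp5 (839 bp) and Jarid2 (526 bp). With the wider 50% of each set this H3.3 call did not pass (odds ratio 1.14, exact adjusted p = 0.696).

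Genes of other cell types and silent gene families were mostly bare. None of the 20 2-cell-like genes, which mark a rare totipotent-like state, had H3K27ac (0 to 16.8%, Fisher's exact test, adjusted p = 2.14e-04) or H3.3 (adjusted p = 0.0706), although several, such as the Zscan4 and Tcstv genes, are near-identical copies in which short reads are hard to place. Of 30 adult-tissue genes, 3 had H3K27ac (10.0%, odds ratio 0.175, exact adjusted p = 0.00203), namely Mog (8415 bp), Mb (7512 bp) and Apoa1 (554 bp), and Sftpc alone had H3.3 (298 bp, list adjusted p = 0.0854). Of 20 fibroblast and feeder markers, 3 had H3K27ac (odds ratio 0.278, exact adjusted p = 0.0453), at Fn1 (1765 bp), Tagln (1564 bp) and Thy1 (213 bp), and 4 had H3.3 (adjusted p = 0.579), widest at Pdgfra. Against shifted regions the H3K27ac calls of these 3 lists did not pass. The means there were 2.08 genes for the 2-cell-like, 3.50 for the adult-tissue and 2.36 for the fibroblast list (permutation, adjusted p = 0.379, 1 and 0.929). The collagen genes Col1a1, Col1a2 and Col3a1 had neither. Olfactory receptor genes had H3K27ac at 3 of 1110 (exact adjusted p = 2.44e-236) and H3.3 at 1 (Olfr94, adjusted p = 4.74e-83). Vomeronasal receptor genes had H3K27ac at 5 of 355 (exact adjusted p = 2.65e-66) and H3.3 at 2 (Vmn1r4 and Vmn2r29, adjusted p = 2.29e-23). Vomeronasal genes lie in clusters, and the H3.3 call did not pass with members at least 1 Mb apart (2 of 44, odds ratio 0.25, exact adjusted p = 0.0521) or against shifted regions (permutation, adjusted p = 0.773).

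Imprinted genes had short H3.3 regions at 5 of 24 (20.8%, odds ratio 1.39, Fisher's exact test, adjusted p = 0.590), which were Peg10 and Sgce with a shared region of 224 bp, Zrsr1, Cdkn1c and Grb10. H3K27ac was found at 4 (16.7%, odds ratio 0.315, exact adjusted p = 0.0436), which were Mcts2 (5538 bp), Zrsr1 (959 bp), Inpp5f (947 bp) and Kcnq1ot1 (543 bp). With regions counted anywhere in the gene, 9 of the 24 had H3.3 (odds ratio 2.46, exact adjusted p = 0.0484), a call that the gene ends do not give. Zinc finger genes were marked somewhat more often than other genes, with H3.3 at 86 of 397 (21.7%, odds ratio 1.47, exact adjusted p = 0.00489, but 0.265 at an odds ratio of 1.22 with the wider 50% of each set), widest at Zfp503 (7487 bp), and H3K27ac at 242 (61.0%, odds ratio 2.5, adjusted p = 2.11e-18), widest at Zfp532 (41598 bp).

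Across the 18 lists, H3.3 was more frequent than among other genes in 10 and less frequent in 2, and H3K27ac was more frequent in 9 and less frequent in 8. Within the genes that have an H3K27ac region, H3.3 was more frequent in 0 of the 17 lists that enter (Fisher's exact test), and in 1 of them at an unadjusted p under 0.05. Of the lineage regulators only Mixl1 enters that background, and among the chaperone genes the odds ratio was 5.30 (exact adjusted p = 0.272). The calls of fewer H3K27ac genes in the imprinted and fibroblast lists, whose adjusted p-values lie just under 0.05, did not pass with the wider 50% of each region set (exact adjusted p = 0.149 and 0.120). The odds ratios there were 0.370 (3 of 24 genes) and 0.288 (2 of 20), close to the 0.315 and 0.278 with all regions, and fewer genes carried the wider regions. The imprinted call depends on the gene end itself. With regions counted anywhere in the gene 12 of the 24 had H3K27ac (odds ratio 0.969, exact adjusted p = 1), and the call also ended with a 2.5 kb window (odds ratio 0.421, exact adjusted p = 0.0736) and with members at least 1 Mb apart (odds ratio 0.337, exact adjusted p = 0.101). The fibroblast call ended with a 500 bp window (odds ratio 0.348, exact adjusted p = 0.125) and with members at least 1 Mb apart (odds ratio 0.295, exact adjusted p = 0.0727).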

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

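Both sets held regions outside the assembled chromosomes, in sequence that no comparison above used, 16 for H3.3 and 13 for H3K27ac. Of these, 2 H3.3 regions covered 12346 bp of the mitochondrial genome, which carries no histones, and 3 H3K27ac regions covered 2635 bp of it. The others lay on unplaced scaffolds, 14 for H3.3 and 10 for H3K27ac. The mitochondrial regions cannot be signal of a histone, so both sets hold some regions that are not. The level in the control libraries was not analysed here, so for the other regions background was not told apart from signal.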

How the results depend on the processing

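Depth, thresholds and replicate agreement could not be varied, since neither set has scores or values per library. No paired analysis was possible because the regions carry no value per library, although wildtype and clone numbers repeat across targets; leaving out a replicate was not run for the same reason. The alternatives with autosomes, whole genes, shifted regions, spaced list members, shared genes left out and touching classes were added after the data were seen. The excess of H3.3 regions touching H3K27ac kept its direction and passed in 6 of 6 alternatives (8.83-fold to 12.4-fold), as did the odds ratio over genes in 3 of 3 (3.72 to 4.08). The share touching was 40.3% when 50% of the H3.3 region had to be covered, 5.34% when 50% of both did, 37.5% in the wider 50% of each set and 21.1% with H3K27ac reduced to 200 bp, each by construction a stricter rule or fewer regions. The gene-end share was, for H3.3 and H3K27ac, 46.0% and 9.16% with a 500 bp window, 74.2% and 28.3% with 2.5 kb, 52.3% and 12.9% with protein-coding genes, 57.5% and 17.5% in the wider 50%, and 64.7% and 22.8% by touching. Joining at 5 kb gave 25368 clusters. Of 271 list alternatives, 218 kept direction and side, 33 lost the call, 13 gained one and 7 reversed. Lists with more H3.3 numbered 6 in the wider 50% and 0 among genes with an H3K27ac region, where lists with fewer also numbered 0. Lists with fewer H3.3 numbered 1 with members at least 1 Mb apart and 1 against shifted regions, against which 2 lists had fewer H3K27ac. The odds ratio for H3.3 reversed among genes with an H3K27ac region for lineage regulators (0.882, 1 gene), primitive endoderm and trophoblast markers (0.529, 2 genes) and imprinted genes (0.882), where few genes remained, and for imprinted genes also in the wider 50% (0.221). Against shifted regions the H3K27ac odds ratio reversed for imprinted genes (1.36) and fibroblast markers (1.32), because random sequence is acetylated less often than a gene end, and the H3.3 odds ratio for adult-tissue genes (2.83).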

Other observations

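The tests of gene families, of X-linked members of families and of nuclease background below, and the additional alternatives, were chosen after the results were seen; the others were written before.

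Gene families defined by the start of their symbol included some with H3.3 and without H3K27ac beyond the listed lineage regulators. Of 366 families of at least 8 protein-coding genes, 16 had more genes with H3.3 and without H3K27ac at their ends than other genes did, and 3 had fewer (Fisher's exact test, adjusted p under 0.05). All 11 Hoxa genes (exact adjusted p = 1.12e-12), all 10 Hoxb genes, all 9 Hoxd genes and 8 of 9 Hoxc genes, which pattern the body axis, were in this state, as were 8 of 9 Pax genes (adjusted p = 2.81e-08). So were 9 of 14 Nkx homeobox genes, 10 of 19 Wnt ligand genes, 9 of 19 Sox genes, 7 of 14 Prdm genes, 6 of 12 Pcdh protocadherin genes, 5 of 8 Lhx genes and 6 of 13 Tbx genes, with Pou, Bmp, Cdkn and Fzd completing the 16. No Hox gene of these 4 families, and no Pax, Nkx, Wnt or Lhx gene of the families tested, had H3K27ac at an end, but 5 of 10 Cdkn, 4 of 14 Prdm, 4 of 19 Sox, 3 of 10 Fzd, 3 of 13 Tbx, 2 of 16 Pou and 2 of 12 Bmp genes did. The protocadherin families Pcdha, Pcdhb and Pcdhga, counted apart from Pcdh, had H3.3 without H3K27ac at 1 of 12, 0 of 22 and 0 of 12 genes. All 12 Pcdhga genes had H3K27ac at an end, but whether these are separate regions or 1 region shared by neighbours was not determined. The families with fewer were Olfr, Vmn and the uncharacterised Gm genes. Hox genes lie in clusters and share regions, so their p-values are too small.

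The state of lineage regulators, with H3.3 and without H3K27ac at 35 of 40 genes, was weighed against 3 technical explanations. Lists of protein-coding genes matched on gene length and on distance to the next gene held a mean of 2.98 such genes and at most 11 (10000 draws, permutation p = 0.0001, the smallest they can give), which argues against length and spacing. Among the regulators at least 1 Mb apart, 31 of 36 were in this state (86.1%, 70.5 to 95.3%, against 5.17% of other genes). Leaving out so few genes could not have lowered the share to that of other genes, so this outcome decides nothing. The spacing shows only that most regulators lie too far apart to share a region. If the H3.3 regions of the regulators came from nuclease cutting at open, active gene ends, genes with the widest H3K27ac regions should carry H3.3 at least as often, but 754 of these 2189 genes did (34.4%, 32.5 to 36.5%), below the lower bound of the regulators (73.2%). If H3K27ac width stands for openness, which was not measured, this argues against such cutting as the whole cause at the regulators only. H3.3 rose with H3K27ac, from 16% of all protein-coding genes to 27.4% of those with H3K27ac and to this 34.4%, so such cutting stays open for H3.3 at acetylated genes. The CpG content of the gene ends, cutting in open but unacetylated chromatin, and the different salt and nuclease conditions of the 2 targets stay open, as no sequence and no control library was analysed here; a hypothesis left for such data is that H3.3 may be held at repressed or poised regulators in these cells.

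The X chromosome held few regions of either set. H3K27ac was present at an end of 12.3% of its protein-coding genes, against 31.5% (chromosome 6) to 48.5% (chromosome 11) on the 19 autosomes, and H3.3 at 2.59%, against 13.0% to 21.4%. The symbol families present on the X do not account for all of this. Among genes for which at least 70% of the other autosomal members of the family had H3K27ac, 46.7% of X-linked genes had it (21 of 45, 31.7 to 62.1%), against 78.9% of autosomal genes (1069 of 1355, 76.6 to 81.0%). H3.3 was present at 8.89% of these X-linked genes (4 of 45, 2.48 to 21.2%), against 25.2% of the autosomal genes (22.9 to 27.6%). Gene content outside these families stays open, and so do differences between X-linked and autosomal members of the same family, since a shared symbol does not match genes on expression. The comparison planned before took its autosomal share from the same genes that chose the families, so it was replaced. Lower depth of the single X of a male line cannot be told apart from a biological difference. The Y chromosome, also single, held 6 H3.3 and 2 H3K27ac regions, which does not separate depth from biology either. The ratio of X to autosomes was 0.144 for the widest 25% of H3K27ac regions and 0.234 for the narrowest 25%, a quotient of 0.616 (0.473 to 0.799). The loss was expected to spare wide regions if depth were the cause, but lower depth also shortens the regions that are called, so a loss of wide regions decides nothing, and no biological explanation was tested.

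H3f3b, which carries alleles labelled A in 3 of the genotypes and is widely expressed, had no region of either set within 1 kb, unlike H3f3a. Its nearest H3K27ac region was 3.69 kb away and its nearest H3.3 region 207.9 kb away.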
